A study of Mus musculus with 14 samples.

How the data were processed

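RNA from the back skin of C57BL/6 mice was sequenced before and at 5 times after exposure to a mixed ultraviolet (UV) source, per the labels. The fur had been depilated, full thickness skin was taken, total RNA was extracted with a phenol reagent (Trizol), and Illumina libraries were made, per the labels' protocols. The UV dose, the strandedness of the libraries, the removal of ribosomal RNA and the time of day of collection are not given in the sources used here. The labels do not say whether the libraries of a group came from separate animals, so every p-value measures the spread between these samples, which may in part be technical.

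The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for 10980 genes in 14 libraries. TopHat2 2.1.0, Cufflinks 2.2.1 and the mouse build mm10 are named, per the submitters' processing notes, without their roles or order. The annotation and the filter that chose the 10980 genes are not given in the sources used here. Every listed gene had an FPKM of 1 or more in at least 2 libraries, so the planned filter at that level removed 0 genes. Library columns were assigned to time points from their headers, which carry no replicate number. There were 2 unirradiated libraries, 2 at 0.5 h, 3 at 2 h, 3 at 6 h, 2 at 12 h and 2 at 24 h.

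The table holds 3 kinds of columns, called library sets here. Set 1 has 6 libraries, 1 per time point, with values of at most 6 significant digits. Set 2 has 5 libraries, at 0, 2, 6, 12 and 24 h, and set 3 has 3, at 0.5, 2 and 6 h; both have values of up to 17 digits, and their headers differ in how they abbreviate the hour. The unirradiated library of set 2 has no such abbreviation and was placed by its mean Pearson correlation, 0.964 with set 2 and 0.889 with set 3. The time points of the 3 sets equal those of the 3 replicate numbers in the sample titles. Set 3 has no unirradiated library. All 28 pairs of libraries of 1 set and different times deviated together from their time-point means, with a correlation across genes of at least 0.411, against at most 0.492 for pairs from different sets. These ranges overlap. Where a time point has 2 libraries their deviations mirror each other, so the pairs are not independent. The set structure was found from the number format, the headers and these correlations before any calls of the fits with and without the set were compared.

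In the 8 libraries of sets 2 and 3, ratios between columns were exact ratios of whole numbers times 1 factor, within a relative tolerance of 1e-12. Whole reads were recovered in this way for 10954 genes, 100% of those above 0 in these libraries, and were used for depth alone. The recovered totals were 12327907 to 13069488 reads per library in set 2 and 14739474 to 15550419 in set 3. In set 1 at most 2 genes shared a ratio, so depth stays unknown there. Listed FPKM totals were 617748 to 700429 in set 1, 441072 to 474898 in set 2 and 513837 to 558821 in set 3. Set 1 lists 52 genes at 0 in all its libraries, 47 of them small nucleolar RNAs, and the other sets list 26 other genes at 0 throughout, so an exact 0 can be a failed estimate. Members of families with near-identical copies (Lce, Sprr, Krtap, hemoglobin and some H2 genes, and the paralogues Krt6a and Krt6b) are uncertain as well, since a read can match several copies. The digits and the zeros of set 1 are signs that it was quantified in another way than sets 2 and 3. Differences between set 1 and the others, above all in such families, may in part come from this.

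Values were tested on the log2(FPKM + 1) scale, which understates the change of genes with low values. The planned test was limma 3.58.1 in R 4.3.3, with group means over all 14 libraries, an intensity trend and 8 residual degrees of freedom, two-sided, with Benjamini-Hochberg adjustment over 10980 genes and a threshold of 0.05. Each time point was compared with unirradiated skin, 6 h with 2 h and 24 h with 6 h, and a moderated F test asked for any change over time. The same model with the library set as a fixed term (6 residual degrees of freedom) was added after the sets had been seen. The median residual SD was 0.335 without the set and 0.155 with it. In the report, a gene "rose", "fell" or "changed" if its limma adjusted p was under 0.05 with the set as a term, and fold changes and standard errors come from that fit.

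Both models were tested on values simulated from the fit with the set as a term, with set effects constant over time and independent noise. The model with the set is favoured by this construction, and set effects that change with time were not simulated. Among the 10980 genes of each simulated table, 100 were shifted by 1 and 100 by 2 on the log2 scale. At 2 h the planned model recovered 24% and 72% of these with 0 false calls, and the model with the set 96% and 100% with 10 false calls. At 24 h the planned model recovered 9% and 74% with 0 false calls. The model with the set recovered 91% and 100% there, with 9 false calls. Recovery was not measured separately for genes with low FPKM, so these shares need not hold for such genes.

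Gene lists were fixed before the data were examined: p53 target genes, nucleotide excision repair, immediate early and AP-1, inflammatory cytokines and chemokines, NF-kB feedback and adhesion, interferon-stimulated genes, EGFR ligands and wound response, NRF2 and metallothionein, heat shock and unfolded protein response, cell cycle, circadian clock, pigmentation, cholesterol and fatty acid synthesis, terminal keratinocyte differentiation, stress and hyperproliferation epidermis, and markers of basal keratinocytes, hair shaft and inner root sheath, sebaceous gland, fibroblasts and matrix, adipocytes, skeletal muscle, neutrophils, monocytes and macrophages, T cells and innate lymphocytes, Langerhans and dendritic cells, mast cells, endothelium and erythroid cells. A further list, of mitochondrially encoded genes, had 0 measured members and was not tested. Coverage of some lists was low, since the deposited table lacks many members. Measured were 3 of 24 neutrophil, 3 of 20 T cell and innate lymphocyte, 3 of 10 erythroid and 5 of 13 mast cell genes. Of the interferon-stimulated genes 9 of 28 were measured, and of the inflammatory cytokines and chemokines 12 of 34. A change of such a list describes these few members alone. The 28 lists were tested with camera at the preset correlation of 0.01, adjusted over 140 pairs of list and time point. Camera with an estimated correlation and the rotation test fry were alternatives. In a simulation at 2 h that shifted 1 list by 0.5 on the log2 scale, both models called it and 0 other lists. Its noise was independent between genes, so it did not test false calls of lists whose genes vary together.

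Named genes follow a rule fixed before the data were examined. Per comparison with unirradiated skin it takes the 6 largest rises and falls with a mean FPKM of at least 1 and libraries that do not overlap, up to 4 called members per list, and a fixed set given whatever their test. The other comparisons take the 5 largest rises and falls. Some genes it takes are not used here. The planned fit called no gene in these comparisons, so the rule was applied to the fit with the set as a term. Gene locations are from GENCODE M21 (GRCm38, the assembly behind mm10), in which 10663 of the genes (97.1%) were found by symbol.

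Alternatives covered the pseudocount, the filter, quantile and median-of-ratios scaling, the variance model, the libraries in the fit, a fold minimum, a muscle or hair covariate, and each library left out in turn. Standard errors of a median gap between groups of genes and of correlations with gene length are from 1000 and 200 bootstrap draws over genes. Those beside list medians and list differences between sets are standard errors of the mean over genes. They take the genes of a list as independent. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.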

Results

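The transcriptome of full thickness mouse back skin was measured over the first day after UV irradiation, in 14 libraries: 2 from unirradiated skin, 2 at 0.5 h, 3 at 2 h, 3 at 6 h, 2 at 12 h and 2 at 24 h. The series asks how gene expression in skin is reprogrammed after genotoxic damage by UV light. Such samples hold epidermis, hair follicles, sebaceous glands, dermis, fat, blood vessels, immune cells and the thin muscle layer under the skin. Depth was 12327907 to 15550419 reads in the 8 libraries where it could be recovered and is unknown in the other 6.

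Libraries resembled those of their own set more than those of their own time point. Spearman correlations across genes, which are not independent replicates, were 0.948 to 0.988 between different times within a set and 0.830 to 0.926 between sets at the same time. The first 2 principal components, with 43.9% and 33.9% of the variance, separated the sets. PC3, with 6.31%, followed time within sets 1 and 2. Its score went from 18.64 at 0 h to -17.84 at 12 h and -9.95 at 24 h in set 1, and from 22.05 at 0 h to -21.09 at 24 h in set 2.

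**Figure D1:**
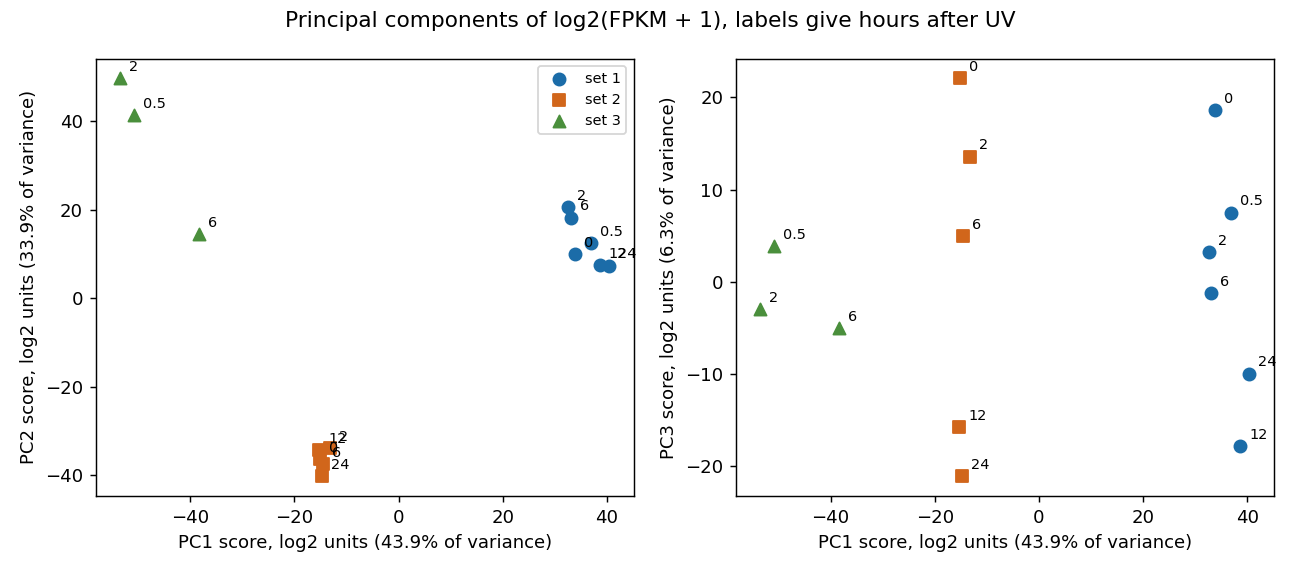
Scores of the 14 libraries on PC1 and PC2 (left) and on PC1 and PC3 (right), with colour and shape for the library set and labels for hours after UV. The sets lie apart on PC1 and PC2, while PC3 falls from 0 h to 12 or 24 h within sets 1 and 2.

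In the planned limma fit, which has no term for the set, 0 genes passed in any of the 7 comparisons. At an unadjusted p under 0.05 it had 333, 660, 615, 494 and 352 genes at 0.5, 2, 6, 12 and 24 h against unirradiated skin, 360 for 6 h against 2 h and 545 for 24 h against 6 h. The F test over time called 1 gene, Klf11 (limma adjusted p = 0.0465), which encodes a transcription factor of the Krüppel-like family. With the library set as a term, limma called 11, 306, 474, 418 and 241 genes at the 5 times, 229 and 342 in the other comparisons, and 540 by the F test. Lower genes made up most of the calls at each time against unirradiated skin. These 5 comparisons share the same 2 unirradiated libraries, so a gene that falls at several times is not an independent repeat.

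Camera called 53 of 140 pairs of gene list and time point in the planned fit and 72 with the set as a term, of which 51 were called in both in the same direction. With an estimated correlation it called 0, with a lowest adjusted p of 0.106 and 0.203, and fry called 6 and 27. The list's median and its camera direction differed in sign in 15 pairs in the planned fit and 11 with the set, and none of these was called. Below, camera values are adjusted p from the planned fit unless the set is named, and medians and members are from the fit with the set.

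**Figure D2:**
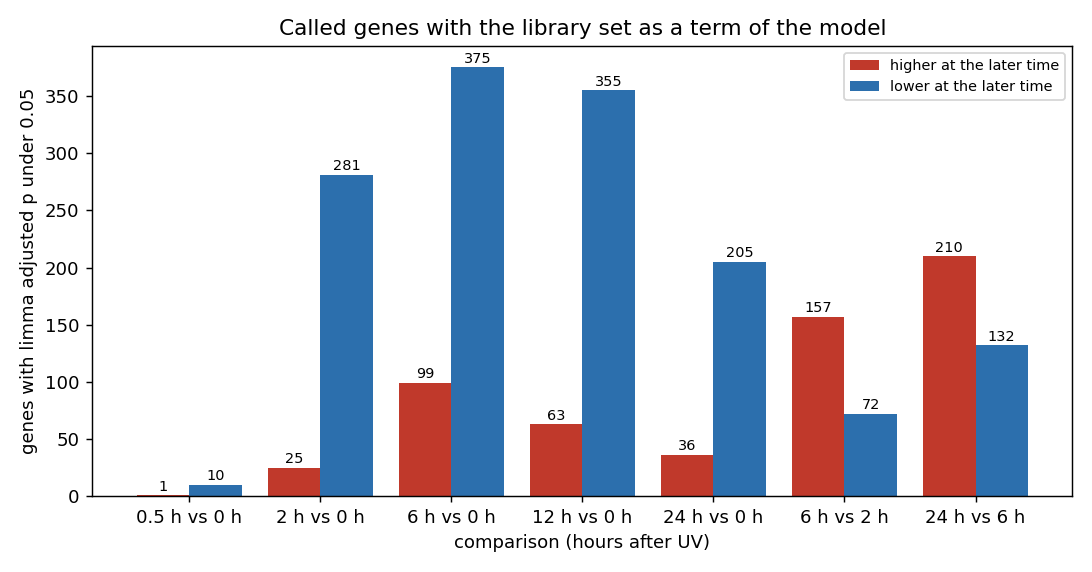
Numbers of genes with a limma adjusted p under 0.05 in each comparison, with the library set as a term, higher (red) or lower (blue) at the later time. Falls outnumber rises against unirradiated skin (281 against 25 at 2 h), and rises outnumber falls for 6 h against 2 h and for 24 h against 6 h (210 against 132, with falls the majority under 2 other scalings).

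At 0.5 h, the genes that fell included some clock, class II antigen presentation and matrix genes, and the precursor of ribosomal RNA rose. The clock genes Per3 and Nr1d2 had changes of -1.52 ± 0.20 and -1.39 ± 0.19 (log2 fold change ± SE). The series has no unirradiated library at a later time, and the time of day of collection is not given. Falls of clock genes, here and at the later times, therefore cannot be told apart from a difference in time of day. Per3 went from 9.10 to 2.06 FPKM in set 1. Cd74, the invariant chain of class II molecules, fell by 1.28 ± 0.15, and H2-Eb1, H2-Aa and H2-Ab1 had changes of -1.38, -1.23 and -1.19. Lum (lumican, a collagen-binding proteoglycan) fell by 1.48 ± 0.20, Tnxb (tenascin XB, a matrix protein) fell by 1.38 ± 0.21 and Cyp27a1 (a sterol hydroxylase) fell by 1.13 ± 0.16. Rn45s, the ribosomal RNA precursor, was the 1 gene that rose, by 1.92 ± 0.27 (limma adjusted p = 0.0312), from 216 to 787 FPKM in set 1. The removal of ribosomal RNA is not given, so Rn45s values at any time may also depend on how much was left in each library. In total 1 gene rose and 10 fell.

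Of the 16 measured circadian clock genes, 2 fell and 14 did not pass at 0.5 h, and 8 fell when adjusted over the list alone; the list's camera adjusted p was 7.7e-05, and 0.117 with an estimated correlation. Of 22 fibroblast and matrix genes 1 fell (19 adjusted over the list alone), with a median of -0.95, a camera adjusted p of 6.6e-09 and an adjusted p of 0.322 with an estimated correlation. Of 11 Langerhans and dendritic cell genes, 4 fell (7 adjusted over the list alone); this list passed with the set as a term (1.5e-09; adjusted p = 0.235 with an estimated correlation) and not in the planned test (0.363). Camera also placed terminal keratinocyte differentiation (0.00321), interferon-stimulated genes (0.0360) and adipocyte genes (0.0354) lower, and immediate early genes (0.00167) and sebaceous gland genes (0.0275) higher, with 0 members past the test in each. With an estimated correlation the adjusted p of these 5 lists was 0.607, 0.193, 0.417, 0.584 and 0.584. The immediate early and sebaceous calls were lost with the set as a term (0.115 and 0.562), and within set 1 the medians of these lists were -0.10 and -0.36, opposite to the calls; without the 0.5 h library of set 3 the planned sebaceous call was lost, with camera's direction lower and a median of 0.0161.

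With the set as a term, camera placed 8 more lists apart at 0.5 h. Monocyte and macrophage genes (1.5e-07, 10 of 13 adjusted over the list alone), basal keratinocyte genes (2.1e-05), NF-kB feedback genes (0.00557), stress and hyperproliferation genes (0.0206) and EGFR ligand and wound genes (0.0266) lay lower, although the stress and hyperproliferation list had a median of 0.002 within set 1, against -0.44 in the fit. Pigmentation (2.1e-05), cell cycle (6.8e-04) and nucleotide excision repair genes (0.0170) lay higher, the last with a median of 0.11. With an estimated correlation the adjusted p of these 8 lists lay between 0.261 and 0.587. The 0.5 h comparison rests on set 1 for a library pair within a set, because set 3 has no unirradiated library. The class II genes show this, with H2-Aa at 56.5 FPKM in set 1 and 172 in set 3 at 0.5 h, against 133 and 164 in the unirradiated libraries. Leaving out 1 library gave between 0 calls (without the 0.5 h library of set 1 or the 6 h library of set 2) and 25 (without the 6 h library of set 3).

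At 2 h, 25 genes rose and 281 fell. Rn45s rose by 1.60 ± 0.24. Klf11 rose by 1.33 ± 0.15 (adjusted p = 0.00829), from 3.98 to 12.0 FPKM in set 1 and from 4.07 to 11.6 in set 2. Zfp36, which encodes a protein that destabilises cytokine transcripts, rose by 1.22 ± 0.26, Arc by 0.99 ± 0.21, Ier3 by 0.87 ± 0.19 and the kinase gene Pim3 by 0.85 ± 0.11. Without the unirradiated library of set 2, Zfp36 and Arc were higher by 0.71 and 0.58, and each kept its call in 5 of the 14 fits that left out 1 library. The largest falls were in the clock output gene Dbp (fell by 2.38 ± 0.45), the cornified envelope genes Hrnr (-2.29 ± 0.53), Kprp (-2.01 ± 0.32) and Lce1i (-1.65 ± 0.37), the EGFR ligand gene Btc (fell by 1.81 ± 0.27) and the adhesion gene Chl1 (fell by 1.68 ± 0.21).

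Of the 33 measured immediate early and AP-1 genes, 6 rose at 2 h, among them Ier2 (1.01 ± 0.18) and Junb (1.003 ± 0.22, or 0.58 without the unirradiated library of set 2), and 27 did not pass; 12 rose when adjusted over the list alone. Camera placed the list higher (6.6e-09; adjusted p = 0.322 with an estimated correlation), but its median change was 0.12 within set 1 and 0.62 within set 2. Atf4, a transcription factor of the integrated stress response, rose by 0.52 ± 0.10, the 1 gene of 22 in the heat shock and unfolded protein list that passed. In the circadian list 5 of 16 fell, and adjusted over the list alone 8 fell and 1 rose. Besides Dbp the falls included Per3 (-1.46), Per2 (-1.24) and Tef (-1.04). Its camera adjusted p was 0.00336, and 0.193 with an estimated correlation.

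Genes of epidermal anchoring were among the falls at 2 h. Of 16 basal keratinocyte and hemidesmosome genes 5 fell (8 adjusted over the list alone), including Dst (-1.35), Col17a1 (-1.20), Itga6 (-0.87) and the stem cell marker Lgr6 (-0.72), with a camera adjusted p of 0.00933, or 0.124 with an estimated correlation. In the fibroblast and matrix list 4 of 22 fell (19 adjusted over the list alone), with Lum at -1.60, Col1a2 at -1.38, Sparc at -1.10 and Dcn at -0.67; its camera adjusted p was 3.6e-06, and 0.465 with an estimated correlation. The list's median was -0.34 in set 1 and -1.36 in set 2, and without the unirradiated library of set 2 Col1a2 and Sparc changed by -0.91 and -0.68. Terminal differentiation genes lay lower (2.9e-04; adjusted p = 0.584 with an estimated correlation), with 1 of 29, Hrnr, past the test (6 adjusted over the list alone). Interferon-stimulated genes did so too (0.0235; adjusted p = 0.182 with an estimated correlation), with 1 of 9, Stat2 (-0.70), past it (5 adjusted over the list alone). The cytokine gene Csf1 (-1.06), Nfkb1 (-0.47) and Ptpn14 (-0.60) fell in the cytokine, NF-kB and p53 lists.

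Monocyte and dendritic cell genes were among the falls at 2 h. Of 13 monocyte and macrophage genes 4 fell, the scavenger receptors Mrc1 (-1.30) and Cd163 (-1.25), F13a1 (-1.20) and the growth factor receptor Csf1r (-1.06); adjusted over the list alone 9 fell and 1 rose. Of 11 Langerhans and dendritic cell genes 5 fell, including Cd209a (-1.21), H2-Eb1 (-1.02), Cd74 and H2-Aa (both -0.99); adjusted over the list alone 8 fell and 1 rose. The median was -0.36 in set 1 and -1.50 in set 2 for the monocyte list, and -0.37 and -1.08 for the dendritic cell list. These lists passed camera with the set as a term (9.7e-04 and 6.7e-05; adjusted p = 0.452 and 0.302 with an estimated correlation) and not in the planned test (0.323 and 0.558). So did hair shaft genes, higher (3.1e-04, with Krt28 up by 0.61 ± 0.13), pigmentation genes, higher (0.0126), and sebaceous gland genes, lower (0.0452), with an adjusted p of 0.579, 0.452 and 0.587 with an estimated correlation. The pigmentation median was -0.03 in set 1 and 0.13 in set 2.

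Skeletal muscle markers lay higher at 2 and 6 h. Their 24 measured genes had a median change of 0.61 at 2 h and 0.60 at 6 h, with 0 members past the test (7 and 0 adjusted over the list alone) and camera adjusted p of 8.0e-08 and 3.5e-07, or 0.301 and 0.322 with an estimated correlation. At 2 h their median was 0.12 in set 1 and 0.81 in set 2. With the mean of the muscle list as a covariate 1 gene was called at 2 h and 2 at 6 h. Of the named genes called without the covariate, 40 at 2 h and 46 at 6 h, all kept their direction with it. The median ratio of their fold with the covariate to that without was 0.944 and 0.963, and that of their SE 1.37 and 1.35. The fold of some genes shrank without a larger SE: Col1a2 went from -1.38 ± 0.28 to -0.81 ± 0.25 at 2 h and from -1.26 ± 0.28 to -0.71 ± 0.25 at 6 h, and Cd209a from -1.21 to -0.74 and from -1.42 to -0.97. Falls made up 91.8% of the 2 h calls, 72.6% after quantile normalization (51 rises, 135 falls) and 78.1% with median-of-ratios scaling (28 rises, 100 falls). In the planned fit these scalings moved the median change of all genes at 2 h from -0.11 to 0.03 and -0.01. With 1 library left out, limma gave from 1 call (without the unirradiated library of set 2) to 558 (without the 6 h library of set 3).

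At 6 h, 99 genes rose and 375 fell, and some cornified envelope genes on chromosome 3 rose while others, already lower at 0.5 h in set 1, fell. Lce3c (GRCm38 chromosome 3, 92944486 to 92945733) rose by 3.02 ± 0.27 (adjusted p = 0.00261), from 5.35 to 35.0 FPKM in set 1 and from 0.913 to 15.9 in set 2, and Lce3d rose by 2.97 ± 0.54. The neighbouring Lce1 genes fell: Lce1j (92788840 to 92790514) by 3.11 ± 0.51, Lce1i fell by 2.98 ± 0.37, and Lce1d, Lce1h, Lce1k and Lce1l had changes of -2.60, -2.54, -2.41 and -2.33. Members of this family are near-identical, so the values of single copies are uncertain. Krt6b, a keratin of wounded and hyperproliferative epidermis, rose by 2.40 ± 0.59, and Ccl20, a chemokine that attracts dendritic cells and lymphocytes, by 2.35 ± 0.33. Angptl4, a secreted inhibitor of lipoprotein lipase, rose by 1.92 ± 0.45, and Rn45s remained higher (1.93 ± 0.24).

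Of the 23 measured stress and hyperproliferation genes 3 rose and 20 did not pass at 6 h (5 rose adjusted over the list alone); the median was 0.61, and camera gave an adjusted p of 1.2e-06, or 0.493 with an estimated correlation. Of 33 immediate early genes 8 rose (13 rose and 1 fell adjusted over the list alone), including Zfp36 (1.10), Ier3 (1.09), Arc (1.09) and the phosphatase gene Dusp6 (0.85), with a camera adjusted p of 1.5e-09, or 0.321 with an estimated correlation, and a median of 0.02 in set 1 and 0.78 in set 2. Zfp36 and Arc were at 0.59 and 0.67 without the unirradiated library of set 2. The EGFR ligand gene Areg rose by 1.501 ± 0.22 while Btc (-1.76) and Hif1a (-0.78) fell. In the unfolded protein list Dnajb9 (0.77) and Atf4 (0.64) rose and Pdia4 (-0.54) fell. Nfil3, a repressor of clock-controlled genes, rose by 0.71 ± 0.13, and Per3 was the 1 clock gene that fell (-0.84); the list as a whole did not pass (0.855).

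Some lipid synthesis genes fell at 6 h. Of 24 cholesterol and fatty acid synthesis genes 6 fell and 18 did not pass (19 fell adjusted over the list alone), among them the desaturase gene Scd2 (-0.99), the elongase gene Elovl4 (-0.99), Cyp51 (-0.62) and Acly (-0.50). The list's median was -0.52 (-0.72 in set 1 and -0.34 in set 2), with a camera adjusted p of 6.9e-07, or 0.193 with an estimated correlation. In the sebaceous gland list 3 of 15 fell (9 adjusted over the list alone), namely Far2 (-1.29), the lipid regulator Pparg (-0.91) and Krt79 (-0.88), with a camera adjusted p of 0.0137, or 0.584 with an estimated correlation. At 12 and 24 h the cholesterol and fatty acid synthesis list did not pass (0.507 and 0.760), and Elovl4 (-0.90 at 12 h) was the 1 member that fell. Without the unirradiated library of set 1, Elovl4, Far2 and Krt79 changed by -0.60, -0.79 and -0.56 at 6 h, and Elovl4 by -0.51 at 12 h.

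Some basal and dermal genes were again among the falls at 6 h, against the same unirradiated libraries. Of 16 basal keratinocyte genes 7 fell (11 fell and 1 rose adjusted over the list alone), including Sostdc1 (-1.25), Col17a1 (-1.24), Lgr6 (-1.12) and Krt15 (-1.03), the last a keratin of follicle stem cells (camera adjusted p = 7.4e-05, and 0.106 with an estimated correlation). Of 22 fibroblast and matrix genes 3 fell, Col1a2 (-1.26), Lum (-1.19) and Eln (-1.03), with 10 adjusted over the list alone (8.9e-05; adjusted p = 0.562 with an estimated correlation). The list's median was -0.26 in set 1 and -0.99 in set 2. Without the unirradiated library of set 2 Col1a2 was at -0.78, and in the planned fit the list was no longer called, with camera's direction higher and a median of -0.0307. Terminal differentiation genes (0.00313, Lce1d as 1 fall of 29, with 8 adjusted over the list alone) and interferon-stimulated genes (0.0354, 0 of 9) lay lower, and p53 target genes higher (0.0174) with 1 member, Ephx1, past the test and lower (-0.61); adjusted over that list alone 3 rose and 2 fell. With an estimated correlation the adjusted p of these 3 lists was 0.607, 0.193 and 0.127. Gtf2h3 (-0.60) was the 1 of 32 nucleotide excision repair genes that fell, and Csf1 fell by 0.92.

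Of the Langerhans and dendritic cell genes 5 of 11 fell at 6 h, including Cd209a (-1.42), H2-Eb1 (-1.05), Cd74 and H2-Ab1 (both -0.92), and 1 of 13 monocyte genes, Csf1r (-1.02). These lists (6.1e-05 and 0.0281), hair shaft genes, higher (6.4e-05), and pigmentation genes, higher (0.0170), passed camera with the set as a term and not in the planned test, with adjusted p between 0.302 and 0.6003 with an estimated correlation. The monocyte median was -0.11 in set 1 and -0.86 in set 2. Hair shaft genes had planned medians of -0.31 at 2 h and -0.18 at 6 h, against 0.18 and 0.31 with the set as a term, and at 6 h their median was 0.34 in set 1 and -0.07 in set 2. Falls made up 79.1% of the 6 h calls, 60.8% after quantile normalization (222 rises, 345 falls) and 63.7% with median-of-ratios scaling (144 rises, 253 falls). Omitting single libraries gave from 2 calls (without the 6 h library of set 2) to 960 (without that of set 3).

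At 12 h, 63 genes rose and 355 fell. Krt6b (chromosome 15, 101676023 to 101680287) rose by 4.43 ± 0.62 (adjusted p = 0.00491), from 1.04 to 79.9 FPKM in set 1 and from 0.0658 to 11.5 in set 2. Lce3c rose by 4.24 ± 0.28 (adjusted p = 1.9e-04), Lce3d by 4.19 ± 0.57 and the small proline-rich genes Sprr2g, Sprr2f and Sprr2i by 4.02, 3.65 and 3.55. Lce1j fell by 4.31 ± 0.54, from 48.4 to 1.17 FPKM in set 1 and from 16.2 to a listed 0 in set 2, and Lce1d, Lce1l, Lce1c, Lce1i and Lce1a2 had changes of -4.10, -3.73, -3.72, -3.65 and -3.41. Sprr2 and Lce copies are uncertain, as above.

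Of 23 stress and hyperproliferation genes 14 rose and 9 did not pass at 12 h (18 rose adjusted over the list alone), with a median of 2.35 (2.88 in set 1 and 2.05 in set 2). Krt6a, a paralogue of Krt6b beside it on chromosome 15, rose by 1.20 ± 0.20. The list's camera adjusted p was 3.8e-32, and 0.117 with an estimated correlation. Of 29 terminal differentiation genes 10 fell and 19 did not pass (15 fell adjusted over the list alone), among them Lce1b (-3.27) and the filaggrin-family gene Flg2 (-3.17), with a camera adjusted p of 1.2e-09, or 0.322 with an estimated correlation. Epgn, an EGFR ligand gene, rose by 2.18 ± 0.49, while Btc (-2.01) and Lamb3 (-0.91), a laminin chain of the basement membrane, fell.

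Damage and stress response genes were among the rises at 12 h. Of 31 p53 target genes 3 rose and 28 did not pass (7 rose and 1 fell adjusted over the list alone): the death receptor gene Tnfrsf10b (0.89 ± 0.21), the cell cycle inhibitor gene Cdkn1a (0.81 ± 0.19) and the nuclease gene Aen (0.69 ± 0.11). Cdkn1a went from 205 to 315 FPKM in set 1 and from 169 to 339 in set 2. Camera gave the list an adjusted p of 0.00351, and 0.110 with an estimated correlation. Of 22 heat shock and unfolded protein genes 4 rose (8 adjusted over the list alone), the chaperone genes Hspa5 (0.71) and Hsph1 (0.64), and Asns and Atf4 (both 0.52), with a camera adjusted p of 1.9e-06, or 0.157 with an estimated correlation. Gadd45g (0.70) was the 1 immediate early gene that rose (list 6.3e-04; adjusted p = 0.584 with an estimated correlation), and the list's median was -0.10 in set 1 and 0.64 in set 2, and -0.131 in the planned fit without the unirradiated library of set 2. Cell cycle genes lay lower (median -0.26, 0 of 32 past the test, 0.0235; adjusted p = 0.584 with an estimated correlation).

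Dermal matrix genes had their lowest median at 12 h, -1.22. Of 22 fibroblast and matrix genes 14 fell (21 adjusted over the list alone), including the collagen genes Col1a2 (-1.93), Col3a1 (-1.92) and Col1a1 (-1.80) and Lum (-1.85). Col1a2 went from 438 to 158 FPKM in set 1 and from 1174 to 221 in set 2, and the list's median was -0.82 in set 1 and -1.61 in set 2. Its camera adjusted p was 1.3e-21, and 0.124 with an estimated correlation. Of 16 basal keratinocyte genes 5 fell, including Col17a1 (-1.33), Dst (-1.14), Sostdc1 (-0.93) and Itga6 (-0.79); adjusted over the list alone 11 fell and 2 rose (0.00443; adjusted p = 0.117 with an estimated correlation). Of 15 sebaceous gland genes 4 fell (7 adjusted over the list alone), Scd3 (-1.41), Krt79 (-1.34), Acsbg1 (-1.14) and Dgat2 (-0.81), with a camera adjusted p of 0.00163, or 0.499 with an estimated correlation. Clock genes again included 5 falls of 16, with Dbp at -2.14, Nr1d2 at -1.36, and Per3 and Nr1d1 at -1.21 (8.4e-04; adjusted p = 0.157 with an estimated correlation).

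Antigen presentation and T cell genes were among the falls at 12 h. H2-Eb1, H2-Ab1, H2-Aa and Cd74 had changes of -1.99, -1.86, -1.85 and -1.70 (adjusted p from 1.9e-04 to 3.7e-04), and 5 of 11 genes of their list fell, with 6 falls and 1 rise adjusted over the list alone (6.7e-04; adjusted p = 0.371 with an estimated correlation). Of the T cell and innate lymphocyte list 3 of 20 genes were measured and 2 fell. These were the T cell receptor component Cd3g (-2.32) and the cytotoxic granule gene Nkg7 (-1.85). The other, Thy1, is also on the fibroblast and matrix list. The T cell list had a camera adjusted p of 1.6e-06, or 0.106 with an estimated correlation. Of 13 monocyte genes 3 fell, Csf1r (-1.65), Lyz2 (-1.38) and F13a1 (-1.29), with 9 falls and 1 rise adjusted over the list alone (0.00946; adjusted p = 0.584 with an estimated correlation). Il1r2 (-1.27), on the neutrophil list, also fell, although that list did not pass (0.281). Hair shaft genes lay higher (2.3e-05; adjusted p = 0.595 with an estimated correlation), with Krt28 up by 0.68. Mast cell genes passed camera with the set as a term alone (adjusted p = 0.0482, and 0.452 with an estimated correlation), with 0 of 5 past the test. Their median was -0.37 in set 1 and -1.38 in set 2. Falls made up 84.9% of the calls, and 68.1% after quantile normalization (152 rises, 325 falls) or 74.5% with median-of-ratios scaling (96 rises, 281 falls). Leaving out 1 library gave from 51 calls (without the 12 h library of set 1) to 814 (without the 6 h library of set 3).

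At 24 h, 36 genes rose and 205 fell, and antimicrobial and acute phase genes joined the keratins among the largest rises. Krt6b rose by 5.80 ± 0.62 (adjusted p = 0.00172) to 276 FPKM in set 1 and 23.6 in set 2. The acute phase gene Saa3 (chromosome 7, 46711998 to 46715700) rose by 4.72 ± 0.52, S100a9, a subunit of calprotectin, by 4.57 ± 0.44, and Lcn2, which binds bacterial siderophores, by 3.81 ± 0.59. S100a9 went from 7.17 to 153 FPKM in set 1 and from 2.95 to 117 in set 2. Sprr2g rose by 3.79 ± 0.53 and Lce3c by 3.66 ± 0.28. The largest falls were Flg2 (fell by 4.08 ± 0.71), Lce1m (fell by 3.79 ± 0.60), Lce1d (-3.34), Lce1c (-3.22), Lce1a2 (-3.19) and Lce1b (-2.86). Without the 24 h library of set 2 these 6 had changes of -2.665, -2.405, -1.98, -1.88, -2.08 and -1.59.

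Of 23 stress and hyperproliferation genes 15 rose and 8 did not pass at 24 h (18 rose adjusted over the list alone), with a median of 2.87; Krt6a rose by 1.83 ± 0.20, from 170 to 657 FPKM in set 1 and from 136 to 452 in set 2. Camera gave an adjusted p of 7.3e-38, and 0.106 with an estimated correlation. Of 29 terminal differentiation genes 12 fell (16 adjusted over the list alone), with a camera adjusted p of 6.7e-18, or 0.182 with an estimated correlation. Timp1, an inhibitor of matrix metalloproteinases, rose by 2.29 ± 0.35, while Btc (-2.02) and Lamb3 (-0.94) fell, so that 1 of 20 wound genes rose and 2 fell (0.00898; adjusted p = 0.221 with an estimated correlation).

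Inflammatory cytokines and chemokines had the next largest positive median at 24 h, 1.15, with 0.48 in set 1 and 1.66 in set 2. Of the 12 measured genes 0 passed over all genes and 7 rose adjusted over the list alone; the camera adjusted p was 3.3e-07, and 0.119 with an estimated correlation. Isg15 rose by 1.23 ± 0.21, the 1 of 9 interferon-stimulated genes that passed (0.00313; adjusted p = 0.117 with an estimated correlation). Tnfrsf10b (0.99 ± 0.21, or 0.62 without the 24 h library of set 2) was the 1 of 31 p53 target genes that rose, with 5 rises and 1 fall adjusted over the list alone (6.5e-04; adjusted p = 0.106 with an estimated correlation), and Asns (0.53) the 1 of 22 in the unfolded protein list, of which 10 rose and 1 fell adjusted over the list alone (2.8e-04; adjusted p = 0.254 with an estimated correlation). NRF2 and metallothionein genes passed with the set as a term alone, with 0 of 20 past the test (0.0457; adjusted p = 0.302 with an estimated correlation).

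Langerhans and dendritic cell genes reached their lowest median at 24 h, -1.36, with -0.89 in set 1 and -1.90 in set 2. Of 11 genes 6 fell (7 fell and 1 rose adjusted over the list alone), with H2-Aa at -2.02, H2-Eb1 at -2.01, Cd74 at -1.87 and H2-Ab1 at -1.80. The list's camera adjusted p was 2.5e-07, and 0.182 with an estimated correlation. Cd3g (-2.12, or -1.29 without the 24 h library of set 2) and Nkg7 (-1.63) were still lower (3.2e-05; adjusted p = 0.106 with an estimated correlation). On the neutrophil list, of which 3 of 24 genes were measured, Il1r2 and Wfdc21 fell (both -1.57). Adjusted over the list alone, 2 fell and 1 rose. The remaining gene, Lrg1, went from 23.8 to 57.3 FPKM in set 1 and from 25.0 to 69.3 in set 2. The list's mean was -0.60 against a median of -1.57, and it passed with the set as a term alone (0.0460; adjusted p = 0.439 with an estimated correlation). Csf1r (-1.07) was the 1 of 13 monocyte genes that fell, and the list did not pass (0.724).

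Fibroblast and matrix genes included 6 falls of 22 at 24 h (13 adjusted over the list alone), with Col1a2 at -1.94, Col1a1 at -1.72, Col3a1 at -1.55 and Sparc at -1.27 (1.8e-13; adjusted p = 0.193 with an estimated correlation). Without the unirradiated library of set 2, Col3a1 and Sparc were at -0.97 and -0.84. Of 15 sebaceous gland genes 4 fell, Scd3 (-2.05), Acsbg1 (-1.55), Krt79 (-1.35) and Dgat2 (-0.82), with a camera adjusted p of 3.0e-05, or 0.322 with an estimated correlation. Of 16 basal keratinocyte genes 3 fell, Col17a1 (-1.33), Krt15 (-1.005) and Sostdc1 (-0.93) (0.0460; adjusted p = 0.193 with an estimated correlation). Per3 (-0.97) and Nr1d2 (-0.79) fell, 2 of 16 clock genes with 8 adjusted over the list alone (9.7e-07; adjusted p = 0.106 with an estimated correlation). Hair shaft genes lay higher (0.0109) and skeletal muscle genes lower (0.0130), with 0 members past the test and adjusted p of 0.759 and 0.595 with an estimated correlation. The muscle median at 24 h was -0.52 in set 1 and 0.10 in set 2. Endothelial and erythroid genes passed camera at no time in either fit. Without 1 library at a time, limma gave from 54 calls (without the 24 h library of set 2) to 383 (without the 6 h library of set 3).

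**Figure D3:**
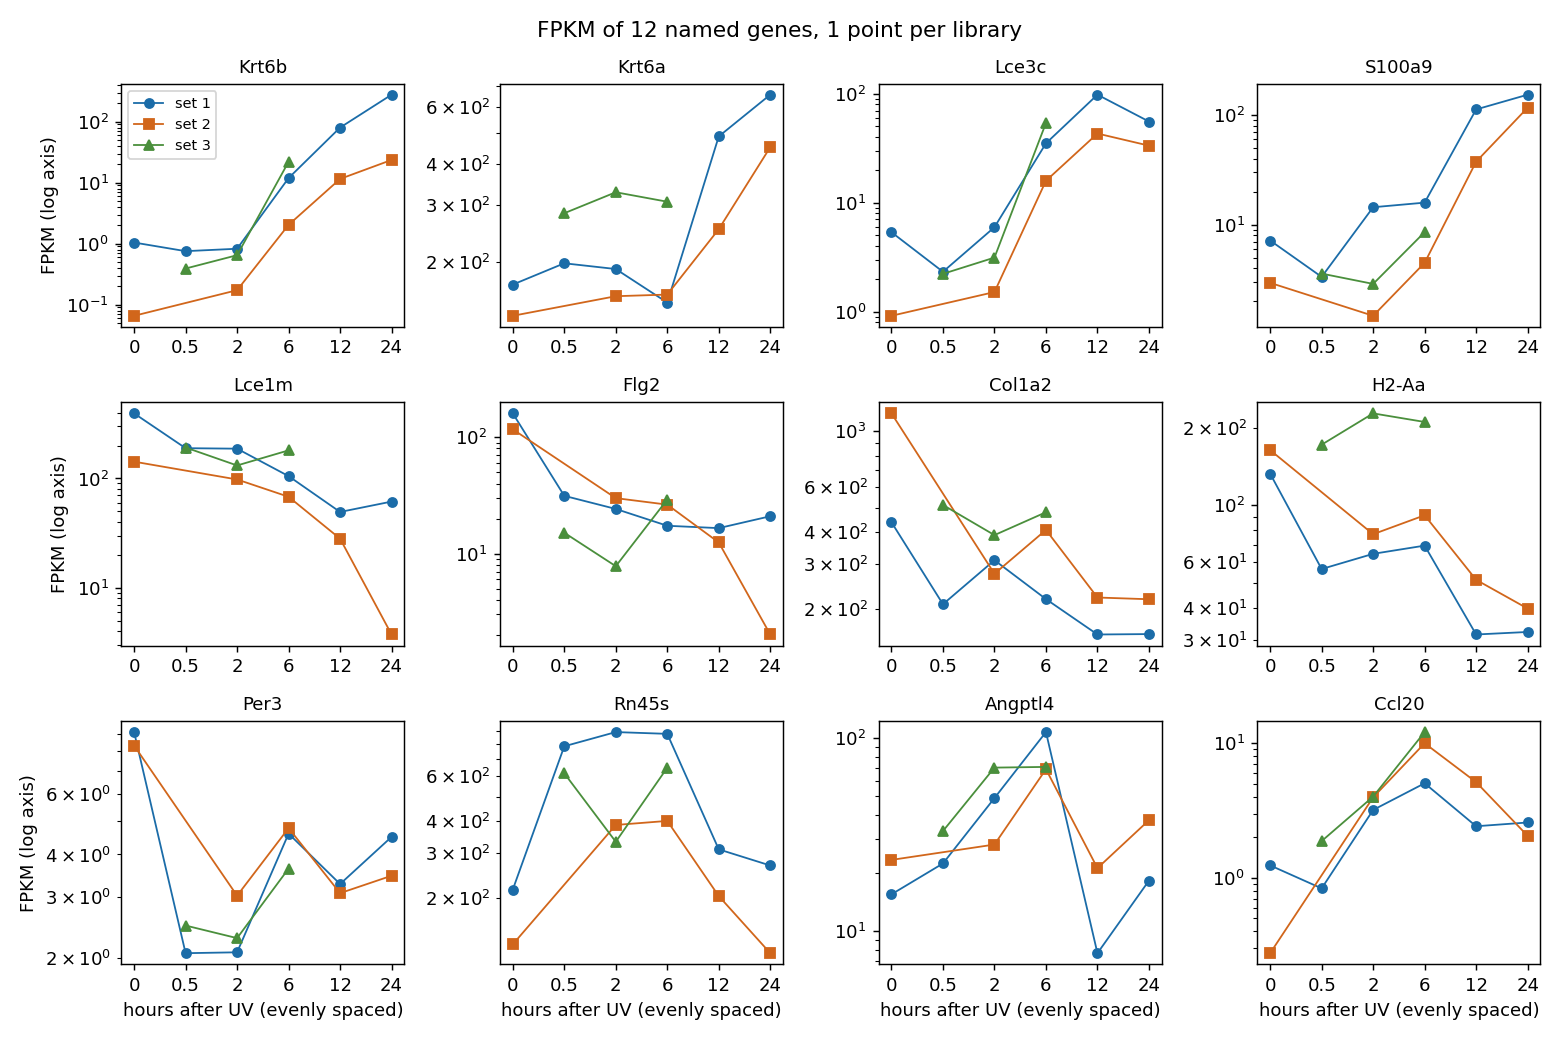
FPKM (log axis) of 12 named genes against hours after UV, 1 point per library, with lines joining the libraries of a set. Krt6b reaches 276 in set 1 and 23.6 in set 2 at 24 h, while H2-Aa ends at 32.2 and 39.7; set 3 has no library at 0, 12 or 24 h.

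**Figure D4:**
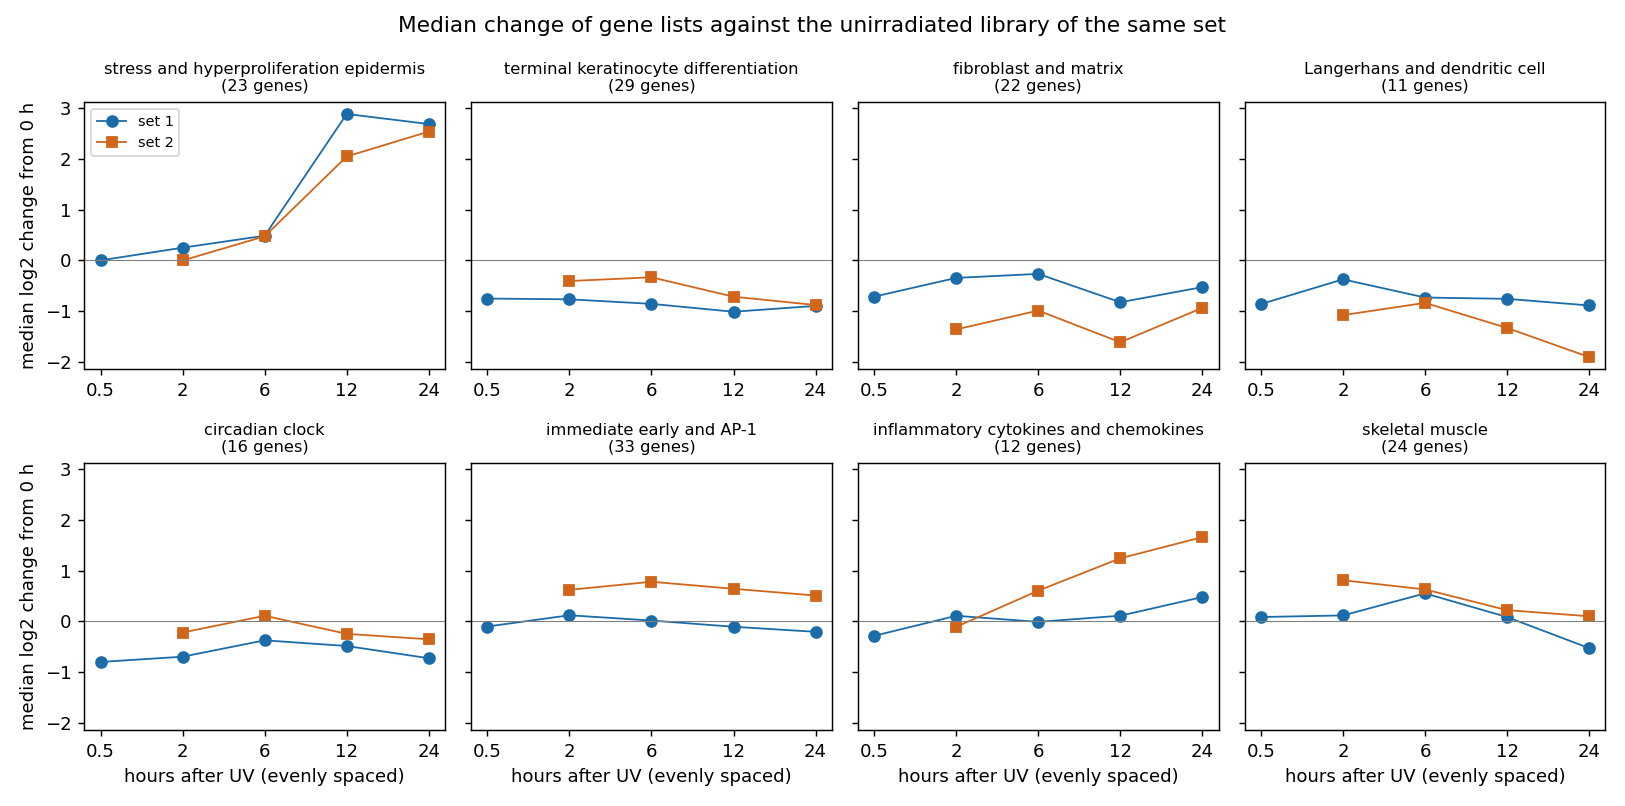
Median log2 change of 8 gene lists in set 1 (blue) and set 2 (orange), each library against the unirradiated library of its own set, so each point is the difference of 1 library from 1 other. Stress and hyperproliferation genes reach 2.69 and 2.54 at 24 h, and inflammatory genes 0.48 and 1.66.

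Between 2 and 6 h, the comparison with 3 libraries in each group, 157 genes rose and 72 fell. Lce3c rose by 2.95 ± 0.23 (adjusted p = 0.00121), Krt6b by 2.66 ± 0.51, Lce3d by 2.65 ± 0.47 and Sprr2g by 2.30 ± 0.43 (1.475 without the 6 h library of set 3). The largest falls were Rnase12 (-1.44 ± 0.26), Fam101a (-0.98 ± 0.21), Mad1l1 (-0.87 ± 0.10), which encodes a spindle checkpoint protein, Cbs (-0.81 ± 0.14), an enzyme of cysteine synthesis, and Mapkap1 (-0.80 ± 0.09), a subunit of mTOR complex 2. Falls made up 31.4% of the calls, 47.2% after quantile normalization (124 rises, 111 falls) and 41.9% with median-of-ratios scaling (129 rises, 93 falls). Leaving out 1 library gave from 8 calls (without the 2 h library of set 3 or the 6 h library of set 2) to 363 (without the 6 h library of set 1).

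From 6 to 24 h, 210 genes rose and 132 fell. Saa3 rose by 3.93 ± 0.49 (adjusted p = 0.00887), S100a9 by 3.80 ± 0.42 (adjusted p = 0.00466), Krt6b by 3.40 ± 0.59, Lce3b by 3.18 ± 0.46 and Sprr2f by 3.15 ± 0.41. Lce1m fell by 2.48 ± 0.57 (-3.89 without the 24 h library of set 1 and -1.12 without that of set 2), the kinase gene Mylk4 fell by 2.202 ± 0.42, the mitochondrial carrier gene Ucp3 fell by 2.17 ± 0.36 and the epidermal keratin gene Krt77 fell by 2.07 ± 0.37. Krt77 went from 648 to 290 FPKM in set 1 and from 608 to 102 in set 2. Falls made up 38.6% of the calls, but 51.4% after quantile normalization (180 rises, 190 falls) and 57.7% with median-of-ratios scaling (115 rises, 157 falls). Omitting single libraries gave from 15 calls (without the 6 h library of set 2) to 611 (without that of set 3), and the muscle covariate gave 2.

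Several genes often followed after UV did not pass in any comparison with unirradiated skin, and the sets differed in their levels. Fos was at 130 FPKM in the unirradiated library of set 1 and at 4.82 in that of set 2; at 2 h it was at 87.1 and 27.6, and at 24 h at 12.8 and 13.3. Il1b was at 1.32 and 0.832 FPKM in the unirradiated libraries and at 1.99 and 31.1 at 24 h, in sets 1 and 2. Cxcl1, a neutrophil attractant, was at 0.216 and 0.388 FPKM before and at 1.28 and 12.51 at 24 h. Mdm2, which encodes the ubiquitin ligase of p53, was at 20.3 and 24.4 FPKM before and at 22.1 and 34.1 at 24 h, and Trp53 at 75.7 and 52.3 before and 78.5 and 61.0 at 24 h. The damage recognition genes Ddb2 and Xpc were at 5.60 and 8.33 FPKM in unirradiated skin of set 1 and at 3.89 and 8.51 at 24 h, and at 10.8 and 7.80, then 6.86 and 6.99, in set 2. Per1 was at 31.7 and 15.4 FPKM before and at 11.3 and 10.3 at 24 h, and Tyr, the pigment enzyme gene, at 29.6 and 42.1 before and 26.2 and 40.5 at 24 h. Ptgs2 and Pomc were not analysed here.

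Changes in set 1 and set 2, each against its own unirradiated library, recurred in part. Over 9238 genes with a mean FPKM of at least 5, the correlation of the changes across genes, which are not independent replicates, was 0.431 at 2 h, 0.564 at 6 h, 0.620 at 12 h and 0.511 at 24 h (Pearson), or 0.493, 0.567, 0.513 and 0.356 (Spearman). Of 200 genes at least 2-fold lower at 12 h in set 1, 93.0% were also lower in set 2, against 46.5% of genes with smaller changes. At 2, 6 and 24 h the share was 93.5%, 92.4% and 83.4%. At 2, 6, 12 and 24 h, 34, 56, 59 and 69 genes were at least 2-fold higher in set 1. Of these, 17.6%, 58.9%, 57.6% and 49.3% were also higher in set 2. Their median change in set 2 was -0.61, 0.37, 0.33 and 0. Of genes with smaller changes, 46.6%, 48.8%, 46.5% and 42.6% were lower in set 2 at these times, so many were higher without a rise in set 1. These shares of rises alone therefore do not show recurrence beyond that of other genes. Of the 34 at 2 h, 20 were hair keratin-associated (Krtap) genes, and all 20 were lower in set 2. Apart from Krtap genes, 6 of 14 rises recurred at 2 h, 33 of 50 at 6 h, 31 of 42 at 12 h and 29 of 40 at 24 h. The Krtap genes as a family, 51 of them, had a median change of 0.89 in set 1 and -0.49 in set 2 at 2 h. Set 1 may have been quantified in another way and Krtap copies are near-identical, so this contrast may be partly technical.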

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

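The comparisons, lists, rule for named genes and most alternatives were chosen before the data were examined. The library set as a term, every alternative that includes it, and the fit without set 3 were chosen after the sets had been seen.

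In the planned fit without the set, the counts of 0 genes in the 7 comparisons (333 to 660 genes at an unadjusted p under 0.05 in limma) stayed at 0 under most alternatives. With the set as a term they became 11, 306, 474, 418 and 241 at 0.5, 2, 6, 12 and 24 h, 229 for 6 h against 2 h and 342 for 24 h against 6 h, and the F test went from 1 to 540 genes. Quantile normalization gave 1 gene at 24 h, 1 for 24 h against 6 h and 3 in the F test. Without the intensity trend there were 2 at 2 h and 1 at 6 h. The F test called 0 with median-of-ratios scaling, with the skeletal muscle covariate and with the hair covariate. Of the gene lists, 53 pairs were called, 0 with an estimated correlation and 6 with fry; with the set as a term there were 72, 0 and 27. The cause of these differences between fits was not tested, except that the set term lowered the median residual SD from 0.335 to 0.155.

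With the set as a term, quantile normalization gave 186 genes and median-of-ratios scaling 128 at 2 h. Fitting only the 2 groups compared gave 652 at 2 h, 32 at 24 h, 5 for 6 h against 2 h and 160 for 24 h against 6 h. The skeletal muscle covariate gave 6 at 0.5 h, 1 at 2 h, 2 at 6 h, 258 at 12 h, 56 for 6 h against 2 h, 2 for 24 h against 6 h and 92 in the F test; the hair covariate gave 599 at 2 h. A fold minimum of 1 on the log2 scale left 88, 107, 203 and 157 genes at 2, 6, 12 and 24 h, 19 for 6 h against 2 h and 99 for 24 h against 6 h, because it removes calls by construction. Without set 3 there were 2 at 0.5 h, 156 at 2 h, 8 for 6 h against 2 h and 321 in the F test. Apart from the fold minimum, the cause was not tested.

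Leaving out 1 library often leaves a group with 1 sample, which is then assumed to vary like the other groups. In the planned fit this gave 0 to 0 genes at 0.5, 2, 6 and 12 h and for 6 h against 2 h, 0 to 25 at 24 h (25 without the 24 h library of set 1) and 0 to 1 for 24 h against 6 h (1 without the same library). The F test gave 0 to 1: it stayed at 1 without the 6 h library of set 3 or either 24 h library, and fell to 0 without any of the other 11. The lists gave 50 to 63 calls.

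With the set as a term the ranges were 0 to 25 genes at 0.5 h, 1 to 558 at 2 h, 2 to 960 at 6 h, 51 to 814 at 12 h, 54 to 383 at 24 h, 8 to 363 for 6 h against 2 h, 15 to 611 for 24 h against 6 h, 113 to 867 in the F test and 66 to 76 list calls. Counts that moved by over 1.5 times are given next, library by library. Without the unirradiated library of set 1 there were 1, 40, 69, 164 and 82 genes at 0.5, 2, 6, 12 and 24 h, 125 for 6 h against 2 h, 222 for 24 h against 6 h and 189 in the F test. Without that of set 2 there were 1, 1, 14, 92 and 62 at the same times, then 123, 221 and 113. Without the 0.5 h library of set 1 there were 0, 123 and 234 at 0.5, 2 and 6 h, then 85, 145 and 288, and without that of set 3 there were 1, 122 and 226, then 85, 144 and 206.

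Without the 2 h library of set 1 there were 109 at 2 h and 277 at 6 h, then 10 for 6 h against 2 h, 175 for 24 h against 6 h and 230 in the F test. Without that of set 2 there were 183 at 2 h, then 35, 218 and 299, and without that of set 3 there were 96 at 2 h, 8 for 6 h against 2 h and 348 in the F test. Without the 6 h library of set 1 there were 261 at 6 h and 363 for 6 h against 2 h. Without that of set 2 there were 0, 116 and 2 at 0.5, 2 and 6 h, then 8, 15 and 125. Without that of set 3 there were 25, 558, 960, 814 and 383 at 0.5, 2, 6, 12 and 24 h, then 81, 611 and 867. Without the 12 h library of set 1 there were 4, 178, 312 and 51 at 0.5, 2, 6 and 12 h, then 86, 213 and 161, and without that of set 2 there were 4, 177, 312 and 87, then 86, 215 and 187. Without the 24 h library of set 1 there were 19 at 0.5 h, 151 for 6 h against 2 h and 179 for 24 h against 6 h. Without that of set 2 there were 19 at 0.5 h and 54 at 24 h, then 151, 16 and 316. The cause was not tested.

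Of 2954 values of genes taken by the naming rule with 1 library left out, 2130 kept their direction and their call, 824 lost the call and 0 reversed. Under the other alternatives 2409 of 2733 kept both and 324 lost the call. Kept under every alternative were 0 of 10 calls of the naming rule at 0.5 h, 0 of 40 at 2 h, 1 of 46 at 6 h (Lce3c), 13 of 54 at 12 h, 8 of 41 at 24 h, 1 of 10 for 6 h against 2 h (Lce3c) and 0 of 10 for 24 h against 6 h. At 12 h these were Lce3c, Sprr2f, Sprr2i, Lce1l, Lce1i, Nr1d2, Col17a1, Lum, Csf1r, H2-Eb1, H2-Ab1, H2-Aa and Cd74. At 24 h they were Saa3, S100a9, Lce3c, Krt6a, H2-Aa, H2-Eb1, H2-Ab1 and Cd74.

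Of the list calls in the planned fit, 688 of 742 values with 1 library left out kept direction and call, 51 lost the call and 3 reversed; under other alternatives 561 of 689 kept both and 128 lost the call. Those that reversed were the fibroblast and matrix list at 6 h and the immediate early list at 12 h without the unirradiated library of set 2 (medians of -0.0307 and -0.131), and the sebaceous gland list at 0.5 h without the 0.5 h library of set 3 (0.0161). With 1 library left out, these 3 medians lay between -0.9715 and -0.0307, -0.131 and 0.689, and 0.0161 and 0.986. In the fibroblast and sebaceous lists it was camera's direction that changed, with medians near 0. With the set as a term, 930 of 1008 and 777 of 936 values kept both, 78 and 158 lost the call, and the skeletal muscle list at 24 h reversed to 0.10 with its own mean as the covariate, which removes that list's changes by construction. For the others the cause was not tested.

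No paired analysis was possible by replicate number, because the library columns carry no replicate number. Comparisons within a library set, and the fit with the set as a term, were made instead. The 3 sets hold the same time points as the 3 replicate numbers, and if each set is the number with its time points, the fit with the set as a term is the blocked fit. The filter on low values removed no gene, so it tested nothing. Not run were the F test with a fold minimum or with only 2 groups, and the alternative for a table of counts, since the table holds FPKM. Depth is unknown in set 1, so what it limits there cannot be given.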

Other observations

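The tests of a smaller share of dermis, of gene length factors, of alignment and counting and of cycling cells were chosen only after the result was seen, as were the Krtap genes and the genes of fat use described here. The 4 genes of fat use given here, Angptl4, Ucp3, Pdk4 and Cpt1a, had their highest value at 6 h in each set, with no gene list or test behind them. Angptl4 and Ucp3 were named by the fixed rule, and Pdk4, which holds back glucose oxidation, and Cpt1a, which admits fatty acids to mitochondria, were picked after their values were seen. Angptl4 was at 15.5 FPKM in unirradiated skin of set 1, 48.9 at 2 h, 107.5 at 6 h and 7.67 at 12 h, and at 23.4, 28.1, 69.0 and 21.2 FPKM at these times in set 2, but in set 3 it was already at 70.3 at 2 h, against 70.9 at 6 h. Pdk4 was at 11.04 FPKM in unirradiated skin of set 1, 19.4 at 2 h, 64.7 at 6 h, 2.97 at 12 h and 1.71 at 24 h. In set 2 it was at 14.96, 50.4, 106, 72.8 and 33.8 FPKM at the same times, and in set 3 it went from 4.69 at 0.5 h to 8.30 at 2 h and 29.4 at 6 h. Cpt1a was at 46.0 FPKM before and 73.3 at 6 h in set 1, at 45.02 and 68.1 in set 2, and at 39.0 at 0.5 h and 61.2 at 6 h in set 3. Ucp3 reached 15.2, 20.5 and 10.7 FPKM at 6 h in sets 1, 2 and 3, from 4.62, 7.71 and 3.81 at 2 h. Skeletal muscle markers were also high at 6 h, with a median change of 0.60, and muscle expresses several of these genes.

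Hair genes differed between the sets and, in set 3 against set 2, between times. Hair shaft genes lay 1.48 lower on the log2 scale in set 3 than in set 2 at 2 h (a median difference of -1.48) and 0.05 higher at 6 h, while set 1 lay 0.97 and 0.999 above set 2. The 51 Krtap genes, which encode proteins of the hair shaft, had a median change of 0.89, 0.46, 0.88 and 1.02 at 2, 6, 12 and 24 h in set 1 and of -0.49, -0.59, -0.23 and -0.13 in set 2. Langerhans and dendritic cell genes lay 1.29 and 0.86 higher in set 3 than in set 2 at 2 and 6 h, and monocyte and macrophage genes 1.27 and 0.75 higher. Stress and hyperproliferation genes differed by 0.13 at 2 h and 1.01 at 6 h between these sets, and lay 1.31 and 0.81 higher in set 1 than in set 2.

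More genes fell than rose 2 h after UV, and the falls were more frequent among long genes: in 5 bins of genes from the shortest to the longest genomic length, 31, 40, 61, 54 and 89 genes fell and 17, 3, 3, 0 and 1 rose. Transcription blocked along long genes by DNA damage was predicted to give a negative correlation of the change with genomic length. Across genes, within bins of exonic length, it was to lie below -0.1 in both sets. The correlation was -0.111 with the set as a term and -0.125 (SE 0.00939) in set 1, but -0.0326 (SE 0.00964) in set 2. This argues against an effect of the predicted size in set 2 at 2 h. The value there still lay below 0, so a weaker effect was not excluded. The same correlation was -0.0936, -0.154, -0.245 and -0.152 at 0.5, 6, 12 and 24 h, so a later block was not excluded. Bias from exonic length or expression level stays open, since the partial correlation of -0.0628 lay between the 2 predictions. Scaling between libraries also stays open as a part of the excess, since the share of falls went to 72.6% under quantile normalization, between the levels predicted with and without it.

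The second pattern is that genes were lower at 0.5 h than in unirradiated skin. Of genes at least 2-fold lower in set 1 at 0.5 h, 145 in number, the median gap to other genes in set 2 was -0.93, -0.87, -1.02 and -0.95 at 2, 6, 12 and 24 h, the highest being -0.869. This is what unirradiated libraries that differ in more than UV dose would give, such as in handling or time of day, but a rapid and lasting effect of UV would give the same, so the gap may come from either. A smaller share of dermis in the irradiated samples was predicted to lower endothelial genes as far as fibroblast and matrix genes. Endothelial genes (median -0.15, SE 0.0680) instead lay 0.795 above fibroblast and matrix genes (-0.95, SE 0.0583). The samples may hold vessels outside the dermis, so this gap cannot exclude a smaller share of dermis. Part of that gap rests on the 0.5 h library of set 3, a set in which endothelial genes lay 0.79 above set 2 at 2 h; within set 1 the medians were -0.32 (SE 0.0660) and -0.71 (SE 0.0608), a gap of 0.392. Decay that went on after 0.5 h stays open: these genes lay a further -0.169 (SE 0.0477) below the others from 0.5 to 2 h in set 3, between the predicted bounds.

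The third pattern is that set 3 stood apart from set 2, although both have the same number format. The libraries of these sets at the same time correlated at 0.830 at 2 h and 0.908 at 6 h (Spearman across genes), below the lowest value of 0.948 within a set. Different gene length factors in quantifying were argued against, since 100% of the genes above 0 in these libraries were whole reads times 1 factor per gene shared by both sets. Alignment and counting of the reads stay open, because a low correlation is the pattern itself and cannot decide between its causes. For fewer cycling cells in set 3, the cell cycle list differed by -0.03 at 2 h (-0.0321) and -0.17 at 6 h, with a standard error over genes of 0.2003 and 0.148. Both values lay on the side of the bound predicted if cycling cells were not fewer. Each was within its standard error of that bound, so fewer cycling cells stays open. Animals, hair cycle stage and library preparation could differ between the sets and were not tested. For 6 h against 2 h, the 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split called 0 genes in the planned fit and the highest other 0, so 10 splits had as many; with the set as a term the real split called 229 and the highest other 8, so 1 did.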
